A study of Mus musculus with 6 samples.

How the data were processed

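Embryo heads were frozen and sectioned, the Lhx6 and Lhx8 territory of the maxillary arch mesenchyme was excised by laser microdissection, total RNA was extracted with a kit for small samples, and the RNA was amplified with the Ovation system before hybridisation to Affymetrix mouse genome arrays, per the labels' protocols. The embryos were matched for sex and somite count and came from a cross of several mouse strains, per the labels' protocols. The labels describe each array as a different embryo, and sections of 1 embryo were pooled into 1 sample.

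The deposited value table holds 1 intensity per probe set and array, for 45101 probe sets, of which 64 are control probe sets. RMA is the one tool named, per the submitters' processing notes. The values themselves are linear, contain zeros and have a mean of 150 on each array after trimming 2% of the probe sets at each end, which RMA does not give, so how the authors summarised these deposited intensities remains unknown. The deposited significance table lists 1061 probe sets with p-values from an unpaired test without multiple testing correction and an absolute fold, kept at p of 0.05 and fold of 1.25, per the file headers. It also holds 6 columns of linear intensities that the file calls raw and whose values differ from the value table. Recomputing the test and the fold from log2 of these intensities matched the deposited p-values to within 5.14e-07 and the deposited folds to within 1.63e-06. A further 6 columns of normalised per-array values were not used. Columns were assigned to samples through genotype and number; a wild-type column bears a number that no sample title has, so it was used as a wild-type replicate without a number.

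Gene names came from the significance table alone, since the other sources used here name no probe set. Of its probe sets 928 carried 1 symbol, 15 several and 118 none, and 854 of the single-symbol probe sets were found by gene identifier in the reference table, 77 of them under a changed symbol. The file's symbols are printed. The remaining 44158 probe sets of the value table were tested without a name, and no gene was named from a probe set with several symbols. As a result every named gene and every gene list rests on probe sets that the submitters had selected on these 6 arrays.

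For the value table, 16 was added to each intensity before taking log2, because zeros have no log; this constant was chosen after the values were seen, and fold changes of dim probe sets are understated on this scale. Control probe sets were left out, and a probe set entered where its mean intensity was over 100 in either group, which left 14446. Group differences were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, group alone in the model, with Benjamini-Hochberg adjustment. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for the remaining steps. An exact permutation test of 3 against 3 arrays cannot give p under 0.1, so none is reported. The significance table was described by its deposited p-values and folds, by the 3 criteria of the series' design text, and by the mean and SD of its intensities.

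Simulated data had 14446 probe sets, of which 200 were changed, and 1 spread per array, taken from the 6 real arrays and shared by all probe sets. The fit called 0% of the 100 probe sets changed 2-fold and 26% of those changed 4-fold. Without the array labelled double mutant 1 it called 37% and 100%, with 13 false calls. Real probe sets differ in spread, which the simulation left out, so these percentages do not carry over to the real data.

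The gene lists, 33 in all, and the rule for naming genes were set before the data were examined. They cover the targeted genes, LIM homeodomain genes, the cell cycle, arch identity, the palate, neural crest, signalling pathways, matrix, cartilage, imprinting, neighbouring cell types, stress, sex-linked genes and ribosomal proteins. The rule names Lhx6 and Lhx8, then up to 12 genes per direction past an adjusted p of 0.05 and a fold of 1.5, or, where fewer than 10 pass, the 10 per direction with the smallest unadjusted p among probe sets meeting the 3 criteria, then up to 4 members of each list, and the CDK inhibitors, because Cdkn1c is known as a subject of this study. The same rule was applied to the significance table after its form was seen, and list members it lists were named, except for an item that is not reported here. Lists were tested in the value table with camera at its preset correlation on 1 probe set per gene against 206 named genes, and in the significance table with Fisher's exact test of direction, two-sided, giving each of 842 genes 1 vote through its brightest probe set; 4 genes were listed in both directions.

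Alternatives set in advance were quantile normalization, a common median, leaving out each array, the replicate number as a block, array weights, other intensity filters, an intensity trend with a robust prior, the ordinary test, 1 value per named gene, other thresholds, an estimated correlation and fry, a rotation test of a list on its own rather than against other genes. Adding 1 or 50 before log2, scaling to the hybridization controls, and the recomputations within the significance table were added after the data were seen.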

Results

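Expression was measured in the mesenchyme of the maxillary arch, the embryonic tissue that forms the upper jaw and the secondary palate, in mouse embryos at embryonic day 10.5. The region taken was the one in which Lhx6 and Lhx8, genes for LIM-homeodomain transcription factors, are normally active, and it was cut from frozen head sections with a laser. There were 3 arrays from wild-type embryos, numbered 1, 4 and 5, and 3 arrays from embryos lacking both genes, numbered 1, 2 and 4. All 6 embryos were female. The comparison asked which genes depend on Lhx6 and Lhx8 in this tissue. Median intensity ran from 19 to 20.5 across the arrays, and 12879 to 13452 probe sets per array had an intensity over 100. The precision of every value is limited by the number of arrays.

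Lhx8 intensity was lower in the double mutants, although a large signal remained in each of them. In the authors' deposited table, which lists 645 selected probe sets as higher and 416 as lower, Lhx8 was 2.55-fold lower with p = 0.00896 by an unpaired test without correction for multiple testing. The intensities in that table were 9032 ± 435 in wild type and 3688 ± 1310 in the double mutants (SD, n = 3), and the double-mutant arrays held 5177, 2711 and 3177. In the value table of all probe sets the wild-type arrays gave Lhx8 intensities of 2063, 1992 and 2241, and the double mutants 2036, 699 and 911. The array labelled double mutant 1, with 2036, therefore lay inside the wild-type range in the value table but below it in the deposited table. The log2 fold change in the value table was -0.93 ± 0.41 (SE), with an unadjusted limma p of 0.0580 and an adjusted p of 0.764. The file places this probe set on chromosome 3 from 153969257 to 153993615, on a build not given in the sources used here. Which part of each gene was deleted is not given in the sources used here either, and a probe set outside the deleted part does not check the genotype. No probe set is named Lhx6 in the files used, so Lhx6 was not analysed here.

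Genes for forkhead transcription factors and for the Notch ligand Jag1 stood among those with higher intensity in the double mutants, and Rspo3, Tbx22 and Ucma among those with lower intensity. In the value table Foxd1 went from 51.8 ± 16.5 in wild type to 335.6 ± 203.9 in the double mutants (SD, n = 3), a log2 fold change of 2.26. Foxd2 went from 64.8 ± 14.9 to 255.6 ± 59.5, Foxp2 from 260.1 ± 48.6 to 1089 ± 511, Foxc1 from 28.8 ± 13.9 to 109.8 ± 28.2, and Jag1 from 92.8 ± 10.1 to 276.6 ± 82.1. Npnt, which encodes the matrix protein nephronectin, had a log2 fold change of 1.65, and Hopx, which encodes an atypical homeodomain protein, one of 2.09. The array labelled double mutant 1 weighed on several of these means. It had 570.9 for Foxd1, against 210.3 and 225.7 on double mutants 2 and 4, and 1676 for Foxp2, against 854.5 and 737.3. Its Jag1 value was also the highest of its group. For Hopx it had 53.3, against 223.7 and 189.9, and its Foxd2 value was also the lowest of its group. The other genes among the 10 with the smallest p on this side, ranked among named probe sets alone, were Slc22a23, Cdc42ep3 and Foxl2os. Their log2 fold changes were 1.40, 1.11 and 1.12. Of the 235 probe sets that met the 3 criteria in the value table, in either direction, 110 were listed in the deposited table. The others had no name and could not be ranked.

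On the lower side, Ucma, which encodes a cartilage matrix protein, went from 104.0 ± 5.6 to 17.3 ± 4.7 (SD, n = 3), a log2 fold change of -1.86. The protocadherin gene Pcdh17 went from 343.4 ± 15.3 to 76.6 ± 32.8, and Rspo3, which encodes a secreted enhancer of WNT signalling, from 206.9 ± 17.7 to 70.9 ± 22.5. Tbx22, a T-box gene known from inherited cleft palate, went from 329.5 ± 89.6 to 117.1 ± 38.0. Id4, which encodes an inhibitor of helix-loop-helix transcription factors, had a log2 fold change of -1.13, and Phyh, which encodes a peroxisomal enzyme, one of -0.96. Cpne8, Tex15 and Rnf180 had log2 fold changes of -1.77, -1.42 and -1.38. For each of these genes the 3 double-mutant arrays lay on one side of the 3 wild-type arrays, which follows largely from choosing them by the smallest p.

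None of these genes passed the test after adjustment. Of 14446 probe sets tested with limma, 0 had an adjusted p under 0.05, and the smallest adjusted p was 0.764. At an unadjusted p under 0.05 there were 245 by limma, and 0 passed by the ordinary per-probe-set test after adjustment, against 346 unadjusted. Both unadjusted counts are a smaller share of 14446 than 0.05, the share expected without any difference if all arrays had equal spread. In the simulated data, where the arrays kept unequal spreads, 2.89% of unchanged probe sets had an unadjusted limma p under 0.05. Leaving out the array labelled double mutant 1 raised this to 5.52% in the simulation, and gave 817 of 13904 in the real data. The low counts therefore do not by themselves show a lack of differences. Without the intensity filter 1646 of 45037 probe sets had an unadjusted limma p under 0.05, where a share of 0.05 among all 45101 would be 2255. Without the array labelled double mutant 1 the count past adjustment was 9 probe sets, 7 higher and 2 lower; named among them were Hopx at a log2 fold change of 2.65, Ebf2 at 2.82, Foxd2 at 1.92 and Npnt at 1.68, and on the lower side Ucma at -1.88 and Pcdh17 at -1.70. Without double mutant 4 it was 2, and with array quality weights it was 1619, a fit in which double mutant 2 had a weight of 20 and the array labelled double mutant 1 one of 0.0375.

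The array labelled double mutant 1 differed from the other 5 in its control probe sets. Its ratio of 3' to 5' signal was 24.8 for Actb and 17.8 for Gapdh, against 1.62 to 1.85 and 1.36 to 1.6 on the other arrays. Its bacterial and phage hybridization controls stood at 3.09 times the wild-type mean. Across probe sets, which are not independent replicates, its log2 intensities correlated with those of the other arrays at 0.597 to 0.674, and the other 5 arrays with each other at 0.945 to 0.975.

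**Figure D1:**
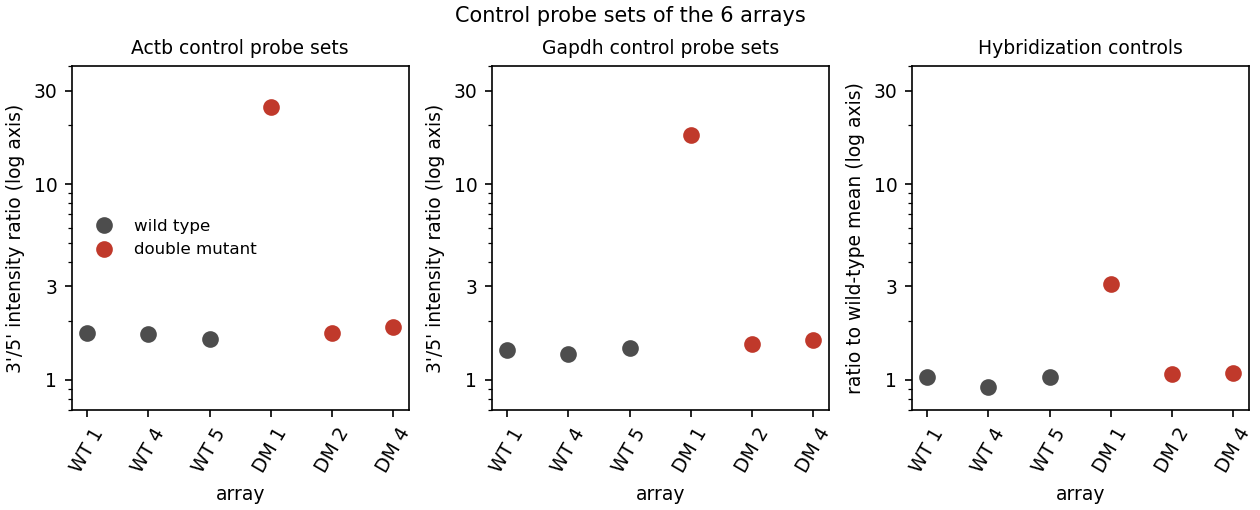
Control probe sets on each of the 6 arrays (WT, wild type; DM, double mutant), 1 point per array on log axes. The left and middle panels plot the ratio of 3' to 5' intensity for Actb and Gapdh, and the right panel the median of the hybridization controls relative to the wild-type mean; the array labelled double mutant 1 stands at 24.8, 17.8 and 3.09, above the other arrays in each panel.

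By the submitters' 3 criteria, an unadjusted p under 0.05, a fold over 1.5 and a mean intensity over 100 in either group, the genes with the smallest p in the authors' deposited table were Ucma, 6.18-fold lower with p = 2.11e-05, and Pcdh17, 2.91-fold lower with p = 2.3e-05. Sema3c, which encodes a secreted semaphorin, was 6.34-fold higher with p = 0.000148 in the authors' deposited table, and Thbs1, which encodes the matrix protein thrombospondin, 1.71-fold higher with p = 0.000541. Sema3c intensity there was 39.1 ± 6.5 in wild type and 248 ± 38.4 in the double mutants (SD, n = 3), and Ucma intensity 403 ± 29.4 and 65.3 ± 7.4. The next genes on the higher side were Slc22a23, Foxp1, Palld, Foxd1, Npnt, Rbms3, Cdkn1c and Ngfr, with folds from 1.63 to 4.92 in the authors' deposited table. On the lower side they were Chrna5, Rasgef1b, Gpt2, Phyh, Cpne8, Rnf180, Cds1 and Eya4, with folds from 1.54 to 6.04 in the authors' deposited table.

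In all, 261 of the listed probe sets met the 3 criteria, 113 higher and 148 lower, and they carried 212 distinct symbol entries, equal to the 212 genes the series' design text gives. Adjusted for all probe sets of the array, the smallest of their p-values would be at most 0.528, and 0 listed probe sets can be shown to pass an adjusted p of 0.05. Leaving out arrays and recomputing p and fold among the listed probe sets gave 118 to 201 probe sets: 135 without the wild-type array numbered otherwise than in the sample titles, 142 without wild type 4, 118 without wild type 5, 151 without the array labelled double mutant 1 and 161 without double mutant 4. Of the 261, 107 to 167 still met the criteria in each of these 6 recomputations, 137 of them without the array labelled double mutant 1. The balance of directions moved as well. Without the array labelled double mutant 1 there were 81 higher and 70 lower, and without double mutant 2 there were 73 higher and 128 lower.

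The same cut-offs applied to the value table with limma's unadjusted p gave 235 probe sets, 124 higher and 111 lower. The intensity cut-off is stricter there, because the 2 tables are on different scales. The wild-type mean of Lhx8 was 2098.5 in the value table and 9032 in the deposited table, and that of Cdkn1c 370.5 and 1439. The counts from the 2 tables are therefore not directly comparable. After shifting each array to a common median, 97 were higher and 139 lower. Scaled to the hybridization controls, a setting chosen after the data were seen, 130 met the criteria, 16 higher and 114 lower. Those controls stood at 3.09 times the wild-type mean on the array labelled double mutant 1, so this scaling lowers that array most. Leaving out wild type 1, 4 or 5 gave 113, 106 and 80, leaving out the array labelled double mutant 1 gave 337, and leaving out double mutant 2 or 4 gave 506 and 659. Of the 261 probe sets of the deposited table, 136 passed the intensity cut-off of the value table and were tested there. Of these, 136 had the same direction there and 98 also met the criteria there. Both tables come from the same embryos, so this overlap is not independent evidence.

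**Figure D2:**
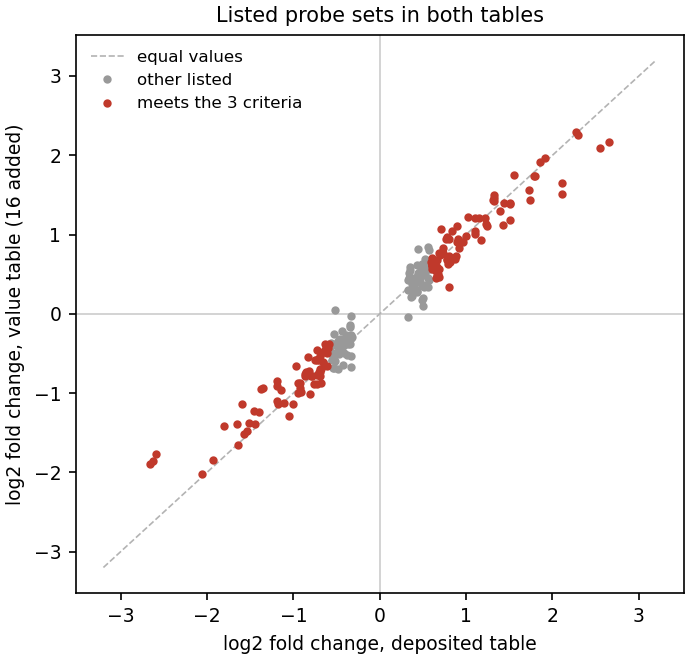
Log2 fold change of 239 listed probe sets in the deposited table (horizontal axis) and in the value table after adding 16 (vertical axis), double mutant minus wild type, 1 point per probe set. Red points meet the 3 criteria in the deposited table and the dashed line marks equal values; 237 of the 239 points have the same sign on both axes.

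Cdkn1c, which encodes an inhibitor of cyclin-dependent kinases, had higher intensity in the double mutants in both tables. Its intensity in the deposited table was 1439 ± 137 in wild type and 2505 ± 282 in the double mutants (SD, n = 3), higher in 3 of 3 double-mutant arrays. In the authors' deposited table it was 1.74-fold higher with p = 0.00302. The value table gave 370.5 ± 60.9 and 730.4 ± 140.1 (n = 3), a log2 fold change of 0.94 ± 0.25 (SE) with an unadjusted limma p of 0.00740 and an adjusted p of 0.764. The file places it on chromosome 7 from 150644241 to 150646901, on a build not given in the sources used here. It was the single listed member of the 8 CDK inhibitor genes. Of 48 genes of the G1/S phases, Exo1 and Ubr7 were listed, both lower, and of 55 genes of G2/M, Nek2 was listed as lower.

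Listed genes of the WNT list were lower in the double mutants, while the file's own annotation gave a mixed set. All 5 listed members of the 41-gene list were lower: Rspo2 and Rspo3, which encode secreted enhancers of WNT signalling, the ligand gene Wnt11, and the pathway's widely used target genes Axin2 and Lef1. Of the 10 listed genes that the file annotates to Wnt receptor signalling, 7 were lower and 3 higher, with an adjusted p of 0.258 by Fisher's exact test over 55 terms examined after the data were seen. Intensities in the deposited table were 647 ± 53.8 in wild type and 213 ± 67.2 in the double mutants for Rspo3 (SD, n = 3), 1244 ± 93.1 and 689 ± 241 for Rspo2, and 2908 ± 160 and 2138 ± 174 for Axin2. For the 5 list members, Fisher's exact test of direction against the other listed genes gave p = 0.00765, two-sided, and an adjusted p of 0.115 over the 15 lists with 3 or more listed genes, 0 of which passed. Among listed genes over intensity 100, as all 5 members are, the exact p was 0.0636 and the adjusted p 0.382. Rspo2, Rspo3 and Axin2 could be tested in the value table, with a median log2 fold change of -0.99 and a camera p of 0.0483. Without the array labelled double mutant 1 the median was -0.54 and the camera p 0.0567, and with array weights the median was -0.42. The adjusted p was 0.290 over 6 lists, and 0.658 with an estimated correlation. Without the intensity filter 5 members gave a camera adjusted p of 0.0429 against 842 listed genes, 523 of them listed as higher. Adjusted over the 3 tested members of the list alone, Rspo3 passed. The listed genes had been chosen by the submitters on these samples, so neither direction nor the count over the list alone is independent evidence.

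Regulators of palate growth were listed in both directions. Barx1, Eya1, Msx1, Shox2 and Tbx22 were lower, and Mn1, Snai1 and the dim Meox2 higher, out of 37 genes on the list. Msx1 intensity in the deposited table was 4554 ± 464 in wild type and 2923 ± 490 in the double mutants (SD, n = 3), Barx1 intensity 771 ± 328 and 266 ± 130, and Shox2 intensity 169 ± 42.9 and 47.1 ± 25.1. Fisher's exact test of direction gave p = 0.163 and an adjusted p of 0.650. In the value table the 6 tested members had a median log2 fold change of -0.43, with a camera adjusted p of 0.472. Adjusted over these 6 alone, Barx1 and Tbx22 passed, but the submitters had picked all 6 at an unadjusted p under 0.05 on these arrays.

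Genes of arch identity gave few listed members. Of the proximal and maxillary list Barx1 and Lhx8 were lower and Foxl2 higher, and of the distal and mandibular list Ednra, Gata3 and Gsc were higher; Foxl2, Ednra and Gsc had means under 100 in both groups. Gata3, a zinc-finger transcription factor gene, had intensities of 792 ± 340 and 1896 ± 348 in the deposited table (SD, n = 3). Of the frontonasal list Aldh1a3, Ebf2 and Pax7 were higher, Ebf2 at 90.1 ± 20.6 in wild type and 700 ± 474 in the double mutants for its brightest probe set, and the other listed genes at intensities under 100. Their adjusted p for direction were 0.819, 0.650 and 0.650 by Fisher's exact test. For the distal and frontonasal lists all 3 listed members were higher, and the unadjusted p was still 0.293 for each. Most listed genes are higher, so with 3 members the test could not have passed on this side.

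FGF-related genes were mixed: Dusp6, the gene of a phosphatase that limits ERK signalling, Etv1 and Barx1 were lower, and Fgfr2, Phlda1, Egr1 and Bcl6 higher. Dusp6 intensity in the deposited table was 3740 ± 381 in wild type and 2316 ± 353 in the double mutants, and Fgfr2 intensity 1185 ± 106 and 1983 ± 344 (SD, n = 3). Of the BMP and TGF-beta list Id4 and Msx1 were lower and Bmp5 and Tgfbi higher. Of the Notch and Eph list Jag1, Efnb2, Heyl and Lfng were higher and Ephb2 lower (p = 0.655 by Fisher's exact test), and over intensity 100 were Jag1, higher, and Ephb2, lower. Of the Hedgehog list Foxd1 and Foxd2 were higher, and of the retinoic acid list Cyp26b1, the gene of an enzyme that degrades retinoic acid, was lower, at 312 ± 83.7 and 65.8 ± 40, while Aldh1a3 was higher. Bcl6, Bmp5 and Aldh1a3 had means under 100 in both groups. Adjusted over the tested list members alone, 5 FGF genes (Barx1, Dusp6, Egr1, Fgfr2 and Phlda1), Id4, Jag1, Foxd1 and Foxd2 passed. Over all probe sets 0 did. The members tested were 6 of 25 FGF, 3 of 36 BMP and TGF-beta, 2 of 30 Notch and Eph, and 2 of 23 Hedgehog genes. The submitters had picked them at an unadjusted p under 0.05 on these arrays, so passing was largely fixed beforehand.

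Extracellular matrix genes were mostly higher among those listed: Bgn, Col12a1, Col5a1, Eln, Thbs1 and Thbs2 were higher and Fbn1 lower, with Col12a1 and Thbs2 under intensity 100. Bgn, which encodes the proteoglycan biglycan, had intensities of 514 ± 45.2 and 775 ± 84.7 in the deposited table for the probe set with its smallest p (SD, n = 3). In the value table that probe set had a log2 fold change of 0.66 ± 0.67 (SE), with an unadjusted limma p of 0.359. The other Bgn probe set had an unadjusted limma p of 0.0855, and the groups overlapped there for both. Fisher's exact test of direction gave an adjusted p of 0.650, and camera gave 0.472 for the 4 genes tested in the value table. Of the neural crest mesenchyme list Ets1, Pdgfrb and Snai1 were higher and Msx1 lower, with a camera adjusted p of 0.472. Of the cartilage and bone list Sox6 and the dim Hapln1 were lower. Of the imprinted list Cdkn1c was higher and Dlk1 lower, Dlk1 at 3251 ± 390 and 1015 ± 593 for its brightest probe set. Adjusted over these 2 tested genes alone both passed, which their selection at an unadjusted p under 0.05 on these arrays largely fixed beforehand.

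Few markers of neighbouring cell types were listed, and most were dim. The Schwann cell precursor genes Erbb3, Foxd3, Ngfr and Sox10 were all higher, and Ngfr, a neurotrophin receptor gene, went from 191 ± 14.7 to 414 ± 77.0 (SD, n = 3), while Sox10 went from 20.3 ± 0.9 to 59.9 ± 31.1. The neuronal genes Isl2, Nefm and Ntrk2 were higher, with each mean under 100. Prss8 of the surface ectoderm and Erg of the endothelium were higher and likewise under 100. Of the erythroid list Gfi1b, also under 100, was higher, of the head muscle list the dim Msc and Pax7 were higher and Eya1 and Lhx2 lower, and Lhx2 was also the listed gene of the brain list. Ldb2 and Isl2 were higher and Lhx2 lower among LIM homeodomain genes and cofactors, and Maf was higher and Sox6 lower among forebrain genes tied to Lhx6 and Lhx8. Of the stress-related lists Cyr61, Egr1, Egr2 and Junb were higher and Hspa1b lower, of which Cyr61 and Egr1 exceeded 100, Pdk1 was lower, and Plk2 higher. None of the macrophage, sex-linked or ribosomal protein genes was listed under a symbol of its own. By Fisher's exact test the adjusted p for direction was 0.650 for both Schwann cell precursors and neurons.

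**Figure D3:**
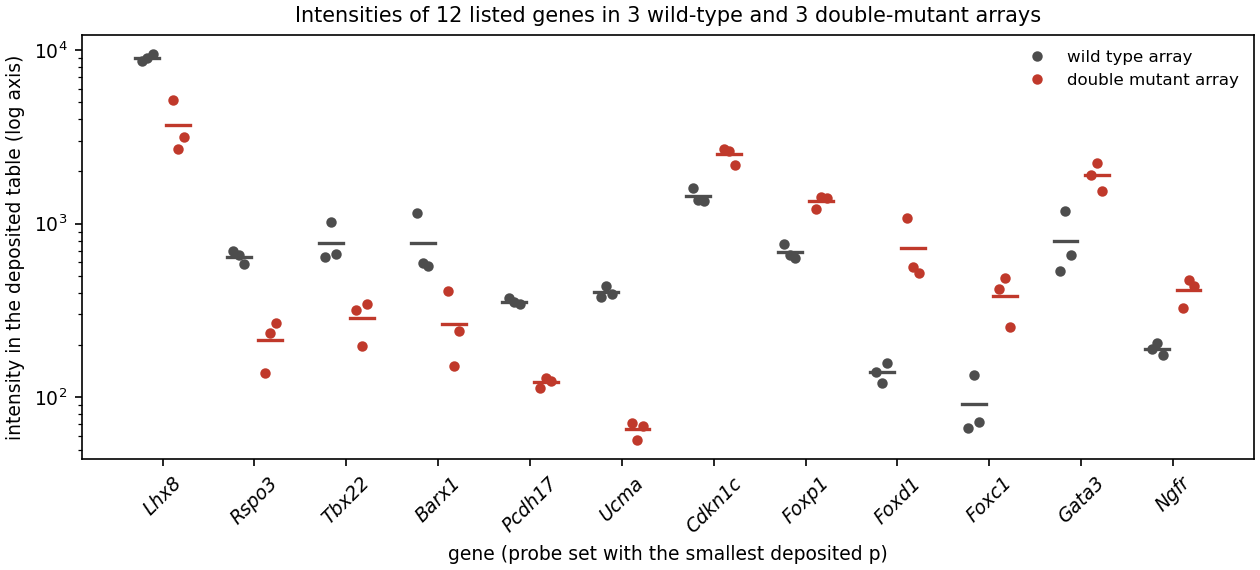
Intensity of 12 listed genes in the deposited table on a log axis, 1 point per array (3 wild type, 3 double mutant) and a bar at each group's mean, for the probe set with the smallest deposited p. Lhx8, Rspo3, Tbx22, Barx1, Pcdh17 and Ucma are lower in the double mutants, and Cdkn1c, Foxp1, Foxd1, Foxc1, Gata3 and Ngfr higher, with no overlap between the groups' arrays.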

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

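The tests of RNA integrity, of a wrong label through correlations and called probe sets, and of the remaining Lhx8 signal in this part were chosen after the results were seen. Control probe sets outside the comparison stood above the wild-type arrays by more than 3 SD on a pair of double-mutant arrays. On the array labelled double mutant 1 the ratio of 3' to 5' signal was 24.77 for Actb (wild-type mean 1.69, limit 1.86) and 17.76 for Gapdh (mean 1.41, limit 1.54), and the hybridization controls stood at 3.09 times the wild-type mean (limit 1.21). On double mutant 4 the Gapdh ratio was 1.6, just over the limit of 1.54.

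The array labelled double mutant 1 stood apart in the value table, and quantile normalization argues against scale or distribution as the whole cause, since its highest correlation with another array after it was 0.7089, under the lowest of 0.942 among the other 5. RNA that was degraded or amplified mostly from its 3' end may account for the pattern, since its 3'/5' ratios were 13.36 times the highest of the other arrays for Actb and 11.12 times for Gapdh. A wrong label alone is argued against as the cause of its distance, since its highest correlation with a wild-type array was 0.651, under the lowest of 0.945 among the other 5. Its genotype stayed open: of probe sets picked from the other 5 arrays, an average of 52.5% placed it on the double-mutant side, with a 95% interval of 45.2 to 59.7 that includes 50, and at 4 of the 9 probe sets called without it the array lay on that side. A biological difference of this embryo was not tested.

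A large Lhx8 signal was left in the double mutants, at 57.3%, 30% and 35.2% of the wild-type mean in the deposited table for the array labelled double mutant 1 and for double mutants 2 and 4. Wild-type cells in the captured tissue would have to come from outside these embryos, since the labels give the double mutants as lacking both genes. In a test of this source, 8 listed genes (Barx1, Chrna5, Cpne8, Cyp26b1, Gria1, Pcdh17, Rasgef1b and Ucma) stood at a smaller share than Lhx8 in every double-mutant array. That count lay between the bounds of 2 and 10 set for the test. Probe sets differ in background and saturation, so shares of different genes are not on one scale and cannot decide on this source. The labelled genotype speaks against it. In the value table the Lhx8 log2 fold change was -1.38 without the array labelled double mutant 1. A transcript still made by the mutant allele and detected by the probe set is a further candidate explanation that stays open, because 1 Lhx8 probe set is named and its place relative to the deletion is not given in the sources used here.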

How the results depend on the processing

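The added constants, the scaling to hybridization controls and the recomputations in the deposited table were chosen after seeing the data. The count of probe sets past an adjusted p of 0.05 was 0 except for 0 to 9 when 1 array was left out (9 without the array labelled double mutant 1, 2 without double mutant 4), 2 with the replicate number as a block and 1619 with array weights, where the weights gave double mutant 2 nearly all of its group's mean. Probe sets meeting the 3 criteria in the value table, 235 in all, ran from 80 to 659 when 1 array was left out, and were 473 with the block, 661 with array weights, 135 by the ordinary test, 135 at intensity over 200, 130 scaled to hybridization controls (16 higher, 114 lower) and 109 at fold over 2. In the deposited table the 261 ran from 118 to 201 with 1 array left out and were 109 at fold over 2. The counts with 1 array left out cover only probe sets already selected on all 6 arrays, so their fall is partly built in. The block rests on numbers 1 and 4, which do not pair the arrays (correlation of deviations 0.07 and -0.08). The Lhx8 log2 fold change stayed below 0, from -0.57 with the block to -1.54 with scaling to hybridization controls, and passed adjustment with array weights alone (-1.53, adjusted p 7.07e-05). No list passed in most settings. The WNT list did without the intensity filter, where its background was 842 listed genes, 523 of them listed as higher. With fry 2 lists did (WNT lower, matrix higher). Their members had been picked by the submitters as different on these arrays, which fry does not allow for. With an estimated correlation both had an adjusted p of 0.658 in camera. Of 661 values of 48 other named probe sets under alternatives, 606 kept direction and side of the threshold, 52 passed adjustment (46 with array weights, 6 without the array labelled double mutant 1) and 3 turned: scaled to hybridization controls, which moved the median of all probe sets to -0.62, Ldb2 was at -0.12, Pdgfrb at -0.11 and Col5a1 at -0.0196. Scaling to the hybridization controls lowers the array labelled double mutant 1 most by construction. Its controls stood at 3.09 times the wild-type mean, against 1.07 and 1.08 on double mutants 2 and 4. The cause was not tested for the other moves, beyond fewer arrays and fewer probe sets where a setting left them out.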

Other observations

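The tests of the gene families and of the gene ontology terms in this part were chosen after the listed genes were seen. Forkhead genes were listed in 1 direction: Foxc1, Foxd1, Foxd2, Foxd3, Foxl2, Foxp1 and Foxp2 were higher, 7 of 7, against 516 higher and 319 lower among the other listed genes. Foxp1 intensity in the deposited table was 689 ± 67.4 in wild type and 1346 ± 117 in the double mutants for the probe set with its smallest p (SD, n = 3), and Foxd2 intensity 187 ± 40.7 and 664 ± 230. A family-wide direction is a hypothesis that this table cannot settle, since the family was picked because its genes stood out here; Fisher's exact test gave p = 0.0488, and 0.0976 adjusted over the 2 families tried. Protocadherin genes showed no such direction, with 5 higher and 4 lower (p = 0.736, Fisher's exact test). The lower ones, Pcdh7, Pcdh10, Pcdh17 and Pcdh19, were the 4 listed at intensities over 100.

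Among 55 gene ontology terms carried by 10 or more of 592 listed genes with annotation, 2 passed Fisher's exact test of direction after adjustment. For DNA repair 11 of 13 genes were lower (adjusted p = 0.0336), and for the response to DNA damage 10 of 12 (adjusted p = 0.0393), with most genes shared. The lower genes include Chek1, Exo1 and Ogg1, which act in checkpoint signalling and repair, and also Eya1 and Eya4, which are better known as developmental transcription cofactors; Eya2, carried by the same terms, was higher. Rad54l, counted as lower, had a log2 fold change of 0.04 in the value table. Among genes over intensity 100 the counts for DNA repair were 9 lower and 1 higher (p = 0.0195 by Fisher's exact test, unadjusted). Other terms ranked ahead of it in that subset, such as regulation of cell proliferation and response to hypoxia, each with 7 higher and 0 lower. No adjustment over the 55 terms was made there. The background of 592 genes had 62.5% higher, while listed genes over intensity 100 were 176 higher and 201 lower. The adjusted results therefore apply to the full background and not to this subset. The terms describe genes that the submitters had selected on these arrays.

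Listed probe sets with both group means under 100 were mostly higher in the double mutants, 433 of 600, while of the 461 over 100 there were 212 higher and 249 lower.

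With 10 splits of the 6 arrays into groups of 3, no share under 0.05 can be reached. Past an adjusted p of 0.05 the real split gave 0 and the highest of the others 0, so that 10 of 10 splits gave a count as large. For the 3 criteria in the value table the real split gave 235 and the highest other 305, which set wild type 1 with the array labelled double mutant 1 and double mutant 2, so that 2 of 10 gave a count as large. Array weights gave 1619 calls in the real split and at most 37 in another, and 0 other splits gave as many. This argues against weights that give as many calls for any grouping. The other splits mix the genotypes, so they cannot tell whether the real calls come from 1 array standing for its group. The real count still rests largely on double mutant 2.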
